A study of Mus musculus with 12 samples.

How the data were processed

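PolyA RNA of the mouse line PT-22 was measured by bulk RNA sequencing in 12 libraries: 3 control libraries and 3 libraries each from 2, 6 and 12 days after treatment with 4-hydroxytamoxifen. Per the submitters' processing notes, the authors used cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 with the genome build GRCm38. The annotation release, the strand use in counting and any filters are not given. The expected counts of RSEM were deposited by the authors as whole numbers without normalization: in 34 to 60 genes per library the count was 0 while the other table held a value above 0, as happens with rounded estimates. The TPM values were made by the authors and deposited as a separate table with 1 column per library. All columns were used (0 left out).

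The tables held 55491 genes, of which 4 had no Ensembl ID. Positions came from GENCODE M21, in which 55227 of the IDs were found and 53417 had the same symbol. The line is named and treated per the labels. Each library's group was taken from its label, and no library was left out. Library totals ran from 4326667 (day 2 B) to 11654959 counts (day 2 C). Between replicates of a group, the chi-square per degree of freedom over genes with at least 20 counts was 2.12 to 7.56, so no pair of libraries was a copy.

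Counts were tested in R 4.3.3 with edgeR 4.0.16: low counts were removed with filterByExpr by group, which left 13513 genes, libraries were scaled with TMM, and 1 quasi-likelihood model with robust dispersion and the group as its term was fitted to all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 0.0577). Contrasts were day 2, day 6 and day 12 against control, the 3 contrasts between treated days, and an F-test across the 4 groups. All edgeR and camera tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 13513 genes, with 0.05 as the threshold. CPM values use TMM-scaled totals, and a prior count of 2 was added for logarithms in the principal components. For Pax8 and Pax2, an exact two-sided permutation test of CPM was run, whose smallest possible p with 3 against 3 libraries is 0.1. Pax8 gave an exact p of 0.1 at each of the 3 days, and Pax2 0.1 at days 2 and 6 and 0.4 at day 12. Where a group had no count, a fold change was computed as a bound against 3 counts over the group, and where it had 1 to 3 counts, as a ratio of counts with a 95% interval. The p-values measure only the spread between these libraries.

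Gene lists were tested with camera (limma 3.58.1) on the edgeR fit with a preset correlation of 0.01, each list against all other tested genes, and adjusted over the 96 tests of 32 lists and 3 contrasts against control. The lists, written from general knowledge, held 1126 symbols, of which 8 had no match in the tables. Members below the filter on low counts were not tested, and the numbers of list genes given below are those tested. They were: nephric transcription factors and PAX cofactors, nephron progenitor and early nephron genes, proximal tubule differentiation, injured or failed-repair proximal tubule, epithelial identity and junctions, mesenchymal genes, extracellular matrix and basement membrane, S phase, G2 and mitosis, p53 targets, the BCL2 family and cell survival, the interferon response, NF-kB and inflammatory genes, glycolysis, fatty acid oxidation and peroxisomes, oxidative phosphorylation, cholesterol synthesis and uptake, the oestrogen response, NRF2 targets, the unfolded protein and integrated stress response, the hypoxia response, immediate early genes, YAP/TEAD targets, TGF-beta targets, WNT targets, cilium and cyst genes, and markers of loop of Henle and distal tubule, collecting duct, podocytes and parietal epithelium, endothelium, fibroblasts and smooth muscle, and leukocytes. In each list the genes past the threshold were counted with adjustment over all genes and adjusted over the list alone. Lists share genes and are not independent. Members also in another list were 23 of 39 for injured proximal tubule, 13 of 32 for TGF-beta targets, 11 of 28 for mesenchymal genes and 11 of 36 for NF-kB and inflammatory genes. The estimated-correlation form of camera and fry were run beside it. The medians of lists did not move when genes without a count in a group were set to their bound (largest shift 0).

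The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule allowed Pax8, Pax2 and Pax5 whatever their values, and some genes it allowed are not reported here. For each contrast against control it allowed the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM over the 6 libraries, no overlap between the groups and a symbol that is not a predicted gene, histone or mitochondrial gene. For contrasts between treated days it allowed the 4 largest of each. For each list it allowed up to 4 members with the smallest p, which could be followed into other contrasts. Other named genes are said to be chosen after their values were seen.

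Because the 3 control libraries enter every contrast with control, the overlap of calls was set beside that of independent lists and beside 20 simulations of unchanged groups against the same controls. With 3 controls, no split into separate control sets of at least 2 was possible. The contrast of day 2 with control and that of day 12 with day 6 share no library and were compared as well.

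Alternatives fixed in advance were relative log expression size factors, no scaling beyond the library total, no filter on low counts, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1), the replicate letter as a replicate block, an adjusted p under 0.01, a fit on only the 6 libraries compared, and leaving out each library in turn. For Pax8 and Pax2 the ratio of mean TPM with a pseudocount of 0.1 and of 1 was computed too. Chosen after seeing the data were thinning of every library to the total of day 2 B, for counts and for lists, and leaving out mitochondrially encoded genes, the related pseudogenes Gm10925 and Gm28661, and CT010467.1. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

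The fit was tested on simulated data with known changes in 50 genes per fold change among 13513 genes at the depth and spread of these libraries. For day 2, day 6 and day 12 against control, edgeR recovered 64%, 64% and 84% of 1.5-fold changes, 86%, 90% and 94% of 2-fold changes and 86%, 88% and 98% of 4-fold changes, and 5.56%, 7.19% and 6.36% of its calls were false. Camera recovered both shifted lists in each contrast, with 2, 1 and 0 false lists, which were 50%, 33.3% and 0% of its calls. Simulated genes were drawn independently, and far fewer changed than were called in the data. Correlation between genes and scaling under so many changes were therefore not tested. Splicing, exon use and allele differences were left out, since the tables hold gene-level values.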

Results

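PT-22 is a mouse proximal tubule epithelial cell line whose labels give it no Pax2, a Pax8 gene flanked by loxP sites and a Cre recombinase that 4-hydroxytamoxifen activates. PAX8 is a paired-box transcription factor of the kidney epithelium, and the study asked what its depletion does to gene expression in these cells. Confluent cells received 1 µM 4-hydroxytamoxifen for 2 days, and polyA RNA was sequenced from untreated control cells and from cells collected 2, 6 and 12 days after treatment. Each of the 4 groups held 3 libraries, lettered A, B and C, which makes 12 libraries. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which can be technical. The design holds no vehicle-treated library and no untreated library from a later day, so drug, Cre activity and time in culture change together with PAX8 depletion.

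The control libraries held 8660496 (A), 7282337 (B) and 9518995 (C) counts. The libraries labelled day 2 held 7386887 (A), 4326667 (B) and 11654959 (C), those labelled day 6 held 10027484, 9068647 and 7482293, and those labelled day 12 held 8653400, 8924305 and 9733611. After a filter on low counts, 13513 genes were tested. On the first principal component, which took 62.8% of the variance, control libraries lay between -60.6 and -57.2, day 2 between -23.6 and -21.7, day 6 between 35.8 and 37.4 and day 12 between 44.3 and 44.9. Mitochondrially encoded transcripts made up 4.25% ± 0.220 of the counts in control, 4.90% ± 0.794 at day 2, 3.91% ± 0.148 at day 6 and 4.41% ± 0.460 at day 12 (SD, n = 3). The nuclear RNA Malat1 took 0.260% ± 0.0140 in control, 0.225% ± 0.00994 at day 2, 0.433% ± 0.0534 at day 6 and 0.270% ± 0.0143 at day 12. Levels below are TMM-scaled CPM (counts scaled to 1000000 per library) as mean ± SD over the 3 libraries of a group, and each gene's adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

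The transcript of the targeted gene was not lower after treatment. Pax8 (ENSMUSG00000026976, GRCm38 chromosome 2, 24420560 to 24475599) stood at 225 ± 3.46 CPM in control, 402 ± 51.0 CPM in the libraries labelled day 2, 256 ± 10.9 CPM at day 6 and 242 ± 10.5 CPM at day 12. The rise at day 2 was 0.83 ± 0.07 (SE) on the log2 scale (edgeR adjusted p = 5.59e-12). The difference at day 6 was 0.18 ± 0.07 (edgeR adjusted p = 0.0181), and it did not pass with limma on log2(TPM + 1) (adjusted p = 0.288), without control A (edgeR adjusted p = 0.0574) or without day 6 C (edgeR adjusted p = 0.0978, the highest of 0.0263 to 0.0978 leaving out each library in turn). At day 12 it was 0.10 ± 0.07 and did not pass (edgeR adjusted p = 0.189). Gene-level counts also take in reads from exons outside a deleted part, and which exons are flanked is not given in the sources used here, so these values check neither the deletion nor the labels. The Cre transcript, chosen after its values were seen, was present in every library at 111 to 319 counts, with 26.2 ± 2.85 CPM in control, 26.0 ± 1.18 CPM at day 2, 23.05 ± 0.949 CPM at day 6 and 27.9 ± 0.564 CPM at day 12.

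Pax2 (chromosome 19, 44756045 to 44837871), whose loss is in the genotype label, had counts in every library, and whether its allele leaves a transcript without a functional product is not given. Its level rose from 46.8 ± 5.78 to 71.6 ± 11.7 CPM at day 2 (edgeR adjusted p = 1.53e-04), 79.0 ± 6.45 CPM at day 6 (edgeR adjusted p = 8.78e-07) and did not differ past the threshold at 50.5 ± 3.71 CPM at day 12 (edgeR adjusted p = 0.427). Pax5 lay below the filter, with 6 to 16 counts per control library and 0 to 3 per treated library. Hnf4a (chromosome 2, 163506808 to 163572910), which directs proximal tubule differentiation, fell from 12.8 ± 2.99 to 1.03 ± 0.529 CPM at day 2 and stood at 0.303 ± 0.166 CPM at day 6 and 2.05 ± 0.718 CPM at day 12. Its log2 fold change at day 2 was -3.78 ± 0.31 (edgeR adjusted p = 6.83e-12).

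**Figure D1:**
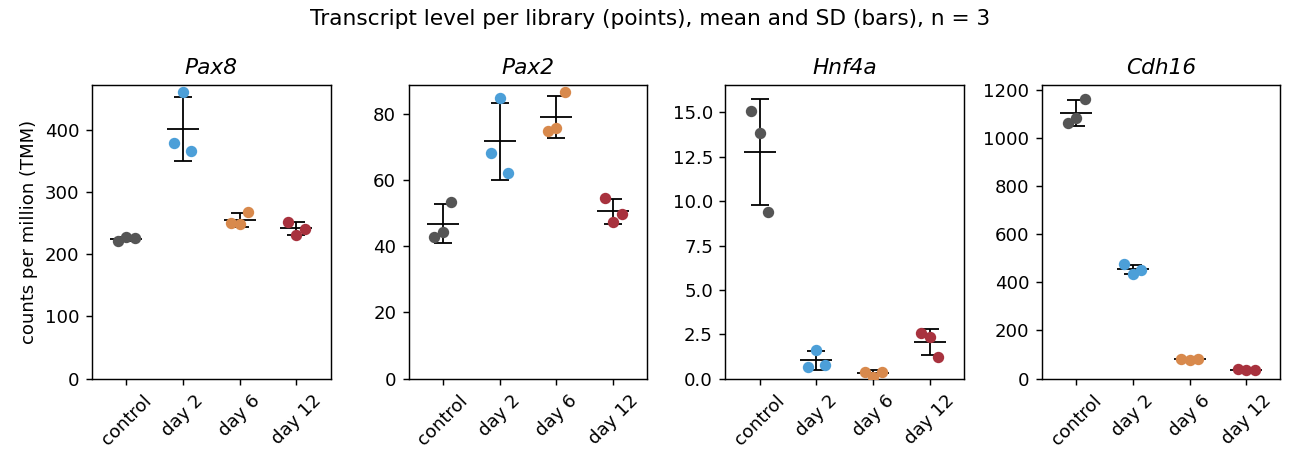
Level of Pax8, Pax2, Hnf4a and Cdh16 in CPM (vertical axes, TMM-scaled, from 0) in the control, day 2, day 6 and day 12 libraries (horizontal axes). Points are single libraries and bars give the mean and SD (n = 3): Pax8 lay at 225 ± 3.46 in control and 401.9 ± 51.0 at day 2, while Cdh16 went from 1103 ± 53.5 in control to 37.9 ± 3.67 at day 12.

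The comparison of day 2 with control asked which genes had changed soonest after treatment. Several proximal tubule and kidney epithelial genes had already fallen. Cdh16, the kidney-specific cadherin, went from 1103 ± 53.5 to 454 ± 19.8 CPM, the tubule cadherin Cdh6 from 729.6 ± 23.1 to 340.2 ± 6.81 CPM, and the brush-border peptidase Anpep from 114 ± 2.75 to 33.1 ± 2.304 CPM. Slc6a18, a brush-border amino acid transporter, fell from 71.1 ± 2.24 to 12.0 ± 2.14 CPM, and the endocytic receptor Lrp2 from 268 ± 17.2 to 112 ± 10.3 CPM. In the same libraries mesenchymal genes rose, among them the intermediate filament gene Vim from 193 ± 14.4 to 530.2 ± 28.4 CPM, fibronectin (Fn1) from 1195 ± 35.8 to 2291 ± 117 CPM and the receptor tyrosine kinase Axl from 187 ± 6.37 to 348 ± 12.9 CPM. Of the 20 genes of nephron progenitors and the early nephron, 9 rose and 6 fell, without passing as a group (camera adjusted p = 0.118). Among them Lhx1 rose from 5.62 ± 0.544 to 24.1 ± 3.97 CPM, Eya1 from 23.7 ± 0.824 to 68.3 ± 3.09 CPM and Wnt4 from 42.2 ± 2.75 to 91.5 ± 2.80 CPM. Each gene named here had an edgeR adjusted p between 3.54e-20 and 4.11e-13.

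The largest rise at day 2 among genes of sufficient level was that of Ly6d (chromosome 15, 74762056 to 74763620), a cell-surface protein, which was 20.7-fold higher, from 1.17 ± 0.583 to 24.3 ± 3.75 CPM (edgeR adjusted p = 5.11e-19). It was followed by the cytochrome P450 gene Cyp1b1 (15.4-fold), Ly6c1 (13.6-fold, uncertain because its near-identical copy Ly6c2 can share reads), the secreted guidance factor Sema3d (12.0-fold), the forkhead factor Foxq1 (7.85-fold) and the semaphorin receptor Plxna2 (5.36-fold). The largest fall was that of Angptl1 (chromosome 1, 156838562 to 156861078), 26.7-fold lower, from 15.2 ± 2.28 to 0.553 ± 0.112 CPM (edgeR adjusted p = 4.13e-14). Hnf4a was 13.8-fold lower, Rasl11b 13.6-fold and the glycosyltransferase gene Gcnt1 11.5-fold. Ifit3b was 11.1-fold lower and Ugt1a1 9.94-fold (edgeR adjusted p = 0.00400). Both are uncertain, since Ifit3b has a near-identical copy in Ifit3 and Ugt1a1 shares exons with its neighbours.

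Of the 26 tested genes of proximal tubule differentiation, 13 fell, 4 rose and 9 did not pass (13 and 6 adjusted over the list alone, camera adjusted p = 1.54e-08). Most symbols of this list were not tested, being too low in these libraries or without a match. Of 42 genes of epithelial identity and junctions, 17 fell, 6 rose and 19 did not pass (19 and 8 adjusted over the list alone, camera adjusted p = 0.00565, adjusted p = 0.158 with an estimated correlation). Members that went up there were the catenins Ctnnb1, from 391 ± 12.7 to 614 ± 19.98 CPM, and Ctnnd1. Among 28 mesenchymal genes, 19 rose, 1 fell and 8 did not pass (20 and 1 adjusted over the list alone, camera adjusted p = 1.50e-16). Inhba, which encodes an activin subunit, rose there from 5.77 ± 0.778 to 19.1 ± 3.34 CPM. Of 39 genes of injured or failed-repair proximal tubule, 20 rose, 7 fell and 12 did not pass (24 and 7 adjusted over the list alone, camera adjusted p = 2.73e-05). S100a6 rose from 283 ± 5.72 to 478 ± 50.2 CPM, while the scaffold gene Akap12 fell from 1567 ± 57.4 to 647 ± 69.2 CPM and Sema5a from 459.6 ± 23.8 to 178 ± 15.001 CPM. TGF-beta targets were also higher as a group: of 32, 16 rose, 5 fell and 11 did not pass (18 and 6 adjusted over the list alone, camera adjusted p = 3.93e-06, adjusted p = 0.0880 with an estimated correlation). Of these 32, 13 are in another list as well, with Fn1 shared with the mesenchymal list, so the 2 results are not independent. Thbs1, a matrix protein, rose from 313 ± 7.90 to 667 ± 27.8 CPM and Pmepa1 from 65.8 ± 5.69 to 132 ± 6.51 CPM, whereas Tgfbi fell from 99.4 ± 9.65 to 32.96 ± 2.22 CPM. Markers of fibroblasts and smooth muscle did not pass as a group: of 14, 5 rose, 2 fell and 7 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.0633), although without control B the camera adjusted p was 0.0401 (0.0401 to 0.172 leaving out each library in turn).

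Inflammatory genes were higher as a group at day 2. Of 36 NF-kB and inflammatory genes, 16 rose, 3 fell and 17 did not pass (20 and 3 adjusted over the list alone, camera adjusted p = 1.42e-06). The NF-kB inhibitor gene Tnfaip3 rose from 8.92 ± 0.340 to 27.4 ± 1.53 CPM, the growth factor Csf1 from 167 ± 3.90 to 268 ± 18.4 CPM and the chemokine Ccl5 from 0.493 ± 0.189 to 6.51 ± 2.07 CPM. YAP/TEAD targets (25 tested) were higher as a group: 14 rose, 5 fell and 6 did not pass (17 and 5 adjusted over the list alone, camera adjusted p = 0.00524, adjusted p = 0.113 with an estimated correlation). Nuak2 rose from 33.4 ± 2.00 to 71.3 ± 4.12 CPM, but Nt5e fell from 73.5 ± 3.80 to 25.1 ± 1.55 CPM. Of 19 WNT targets, 8 rose, 1 fell and 10 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.0110, adjusted p = 0.238 with an estimated correlation), and without day 2 B the camera adjusted p was 0.0503 (0.00491 to 0.0503 leaving out each library in turn). Wnt10a rose from 4.49 ± 1.4999 to 15.005 ± 3.41 CPM and Cd44 from 62.6 ± 4.27 to 93.9 ± 11.6 CPM. Of 62 genes of oxidative phosphorylation, 22 fell, 0 rose and 40 did not pass (24 and 0 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.420 with an estimated correlation), with the ATP synthase gene Atp5b down from 1394 ± 62.5 to 1081 ± 66.6 CPM. The share of mitochondrially encoded transcripts in these libraries was the 4.90% ± 0.794 given above.

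Other lists did not pass at day 2. Among 52 interferon response genes, 19 rose, 6 fell and 27 did not pass (24 and 7 adjusted over the list alone, camera adjusted p = 0.171), with Gbp2 up from 7.06 ± 0.443 to 22.4 ± 2.49 CPM and Ifit3 (uncertain, as above) down from 78.0 ± 2.34 to 7.71 ± 2.67 CPM. For cholesterol synthesis and uptake (32 genes), 7 rose, 2 fell and 23 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.0716), and without control C or day 2 C the camera adjusted p was 0.0333 and 0.0499 (0.0333 to 0.154 leaving out each library in turn). For immediate early genes (28), 9 rose, 2 fell and 17 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 0.0895), and without control C the camera adjusted p was 0.0201 (0.0201 to 0.299 leaving out each library in turn). Of 38 p53 targets, 7 rose, 3 fell and 28 did not pass (7 and 3 adjusted over the list alone, camera adjusted p = 0.611). The growth-arrest gene Cdkn1a fell from 199.5 ± 16.8 to 81.5 ± 4.01 CPM and Gdf15 from 61.6 ± 9.22 to 19.3 ± 4.45 CPM, while Trp53inp1 rose from 36.8 ± 6.89 to 69.7 ± 3.82 CPM. Of 50 S-phase genes, 3 fell, 1 rose and 46 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.633). The rise, of Dscc1, did not pass with DESeq2 (adjusted p = 0.05483). It was also lost without control A, control B, day 2 A or day 2 C (edgeR adjusted p from 0.0608 to 0.07875). The fall of Fen1 was lost without day 2 A (edgeR adjusted p = 0.0823) and that of Pold1 without control C (edgeR adjusted p = 0.0525). Of 54 genes of G2 and mitosis, 6 fell, 1 rose and 47 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.297). For glycolysis (23), 2 rose, 4 fell and 17 did not pass (2 and 4 adjusted over the list alone, camera adjusted p = 0.811). Of 30 NRF2 targets, 8 fell, 8 rose and 14 did not pass (9 and 10 adjusted over the list alone, camera adjusted p = 0.959). Of 40 genes of the unfolded protein and integrated stress response, 10 fell, 6 rose and 24 did not pass (11 and 6 adjusted over the list alone, camera adjusted p = 0.759). For the hypoxia response (25), 6 fell, 6 rose and 13 did not pass (6 and 7 adjusted over the list alone, camera adjusted p = 0.672).

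In all, 2860 of the 13513 genes (21.2%) differed between day 2 and control at an adjusted p under 0.05, 1392 higher and 1468 lower, and 583 of them by at least 2-fold (249 higher, 334 lower). With limma on log2(TPM + 1), 1744 genes passed and 354 of them by at least 2-fold.

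**Figure D2:**
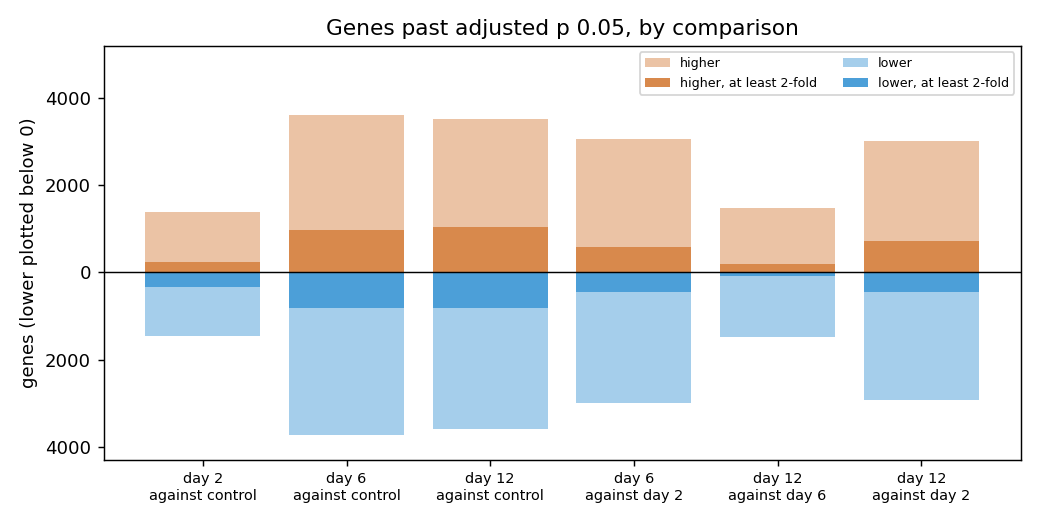
Number of genes past an edgeR adjusted p of 0.05 (vertical axis, genes lower plotted below 0) in each of the 6 comparisons (horizontal axis), with changes of at least 2-fold in the darker shade. Day 6 against control gave 7343 genes, day 2 against control 2860 and day 12 against day 6 2971.

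By day 6 several epithelial genes were far lower. Other epithelial genes rose, as given below. Cdh16 went from 1103 ± 53.5 to 80.5 ± 1.90 CPM. Cdh6 went from 729.6 ± 23.1 to 112 ± 4.59 CPM. Anpep went from 114 ± 2.75 to 8.63 ± 1.03 CPM. Slc6a18 had no count left in any of the 3 libraries. Members of the mesenchymal and TGF-beta lists had risen further: the integrin gene Itgb3 from 27.4 ± 2.04 to 184 ± 1.41 CPM, the myosin light chain gene Myl9 from 39.2 ± 2.26 to 189.5 ± 5.41 CPM, Fn1 from 1195 ± 35.8 to 3577 ± 146 CPM and Thbs1 from 313 ± 7.90 to 1872 ± 35.6 CPM. The transcription factor Maf rose from 39.4 ± 2.77 to 377 ± 9.22 CPM and Eya1 from 23.7 ± 0.824 to 183 ± 8.36 CPM. The glycolysis genes Ldha (lactate dehydrogenase) and Pgk1 fell, Ldha from 1032 ± 118 to 374 ± 16.1 CPM and Pgk1 from 756 ± 52.2 to 311 ± 21.4 CPM. These genes had edgeR adjusted p values between 1.43e-31 and 1.35e-17.

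Several of the largest rises at day 6 were of genes nearly silent in control. The chemokine gene Cxcl15 (chromosome 5, 90794534 to 90803067) had no count in control and 14.7 ± 0.754 CPM at day 6, at least 125-fold higher when control is set to 3 counts over the group (edgeR adjusted p = 1.73e-18). Nts, which encodes neurotensin, was 342-fold higher, from 0.161 ± 0.174 to 58.7 ± 2.40 CPM, and the cationic amino acid transporter gene Slc7a2 195-fold higher, from 0.274 ± 0.0417 to 56.2 ± 4.44 CPM. Pdgfrl was 171-fold higher. Serpind1, a serine protease inhibitor, had 2 counts in control and 435 at day 6, a ratio of 208 (95% counting interval 57.3 to 1725), and the collagenase gene Mmp13 had a ratio of 154 (42.2 to 1274). Slc6a18 (chromosome 13, 73661752 to 73678023) was at least 631-fold lower. Klhl14 was lower by a ratio of 687 (counting interval 190 to 5676), Angptl1 by 137 (46.5 to 666) and Slc13a2os by 157 (42.99 to 1299.5), the last uncertain because it is an antisense transcript and strand use in counting is not given. The potassium channel gene Kcnj16 was 153-fold lower, from 88.5 ± 5.96 to 0.561 ± 0.0323 CPM, and the kinesin gene Kif12 90.1-fold lower.

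Of the 26 proximal tubule genes, 16 fell, 5 rose and 5 did not pass (16 and 5 adjusted over the list alone, camera adjusted p = 2.70e-07), among them the bicarbonate cotransporter gene Slc4a4, from 98.5 ± 2.05 to 38.6 ± 3.23 CPM. Of the 42 epithelial identity and junction genes, 23 fell, 12 rose and 7 did not pass (24 and 12 adjusted over the list alone, camera adjusted p = 1.93e-04, adjusted p = 0.0880 with an estimated correlation). Ctnnb1 rose further, from 391 ± 12.7 to 1264 ± 47.0 CPM, and the junctional adhesion gene F11r from 93.6 ± 0.984 to 238 ± 7.64 CPM. Of 28 mesenchymal genes, 19 rose, 3 fell and 6 did not pass (19 and 3 adjusted over the list alone, camera adjusted p = 8.40e-13). For TGF-beta targets, 24 rose, 3 fell and 5 did not pass (24 and 3 adjusted over the list alone, camera adjusted p = 1.86e-15), with Pmepa1 up from 65.8 ± 5.69 to 300.4 ± 12.3 CPM. Fibroblast and smooth muscle markers did not pass: 9 rose, 4 fell and 1 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.0625). The camera adjusted p for this list was 0.0493 without control B, 0.0357 without day 6 A and 0.0162 without day 6 C (0.0162 to 0.125 leaving out each library in turn). Smooth muscle actin (Acta2, which can share reads with the closely related Actg2) rose from 3.11 ± 0.429 to 65.3 ± 10.3 CPM and Tagln from 1.68 ± 0.357 to 11.3 ± 1.15 CPM. Of the injured proximal tubule genes, 26 rose, 8 fell and 5 did not pass (26 and 8 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.0775 with an estimated correlation). Vim rose there from 193 ± 14.4 to 631 ± 18.3 CPM and the lipid droplet gene Plin2 from 96.6 ± 3.97 to 273 ± 6.31 CPM, while Sema5a fell from 459.6 ± 23.8 to 46.0 ± 5.07 CPM.

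Of 23 glycolysis genes, 20 fell, 0 rose and 3 did not pass (20 and 0 adjusted over the list alone, camera adjusted p = 7.45e-12), including the hexokinase gene Hk2, from 38.6 ± 1.85 to 12.3 ± 1.08 CPM, and Aldoa, from 1151 ± 123 to 451 ± 28.5 CPM. Of 32 genes of cholesterol synthesis and uptake, 26 fell, 1 rose and 5 did not pass (26 and 2 adjusted over the list alone, camera adjusted p = 2.73e-12). The synthase gene Hmgcs1 fell from 435 ± 18.8 to 151 ± 2.62 CPM, the fatty acid elongase gene Elovl6 from 96.1 ± 7.30 to 20.5 ± 1.54 CPM and Sqle from 320.3 ± 8.30 to 133 ± 3.07 CPM. For oxidative phosphorylation, 53 fell, 0 rose and 9 did not pass (55 and 0 adjusted over the list alone, camera adjusted p = 1.28e-07, adjusted p = 0.198 with an estimated correlation), with Atp5b down from 1394 ± 62.5 to 778 ± 8.52 CPM. For the hypoxia response, 15 fell, 5 rose and 5 did not pass (15 and 5 adjusted over the list alone, camera adjusted p = 1.41e-05, adjusted p = 0.0790 with an estimated correlation), with Bnip3 down from 166 ± 3.38 to 55.9 ± 5.57 CPM and the carbonic anhydrase gene Car12 from 76.5 ± 4.39 to 16.6 ± 2.37 CPM. Of 54 genes of G2 and mitosis, 41 fell, 1 rose and 12 did not pass (42 and 1 adjusted over the list alone, camera adjusted p = 1.42e-06, adjusted p = 0.0880 with an estimated correlation). Plk1 fell from 138 ± 6.35 to 73.3 ± 4.68 CPM, the cyclin gene Ccnb1 from 247 ± 2.54 to 152 ± 7.69 CPM and Spc25 from 146 ± 6.33 to 61.99 ± 2.29 CPM. The S-phase list did not pass: 23 fell, 5 rose and 22 did not pass (23 and 5 adjusted over the list alone, camera adjusted p = 0.0877). For the unfolded protein and integrated stress response, 22 fell, 10 rose and 8 did not pass (22 and 10 adjusted over the list alone, camera adjusted p = 0.0128, adjusted p = 0.283 with an estimated correlation), with the chaperone gene Calr down from 954 ± 56.3 to 513 ± 16.0 CPM and Herpud1 up from 49.4 ± 3.08 to 107 ± 4.36 CPM. NRF2 targets did not pass: 17 fell, 6 rose and 7 did not pass (18 and 8 adjusted over the list alone, camera adjusted p = 0.0768). Malat1, the nuclear RNA, took its highest share of the counts in the day 6 libraries, as given above.

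For NF-kB and inflammatory genes, 23 rose, 2 fell and 11 did not pass (23 and 2 adjusted over the list alone, camera adjusted p = 4.35e-05, adjusted p = 0.0880 with an estimated correlation), with Tnfaip3 up from 8.92 ± 0.340 to 63.8 ± 2.73 CPM and the acute-phase gene Saa3 from 0.982 ± 0.0494 to 43.9 ± 8.32 CPM. For the interferon response, 29 rose, 6 fell and 17 did not pass (29 and 6 adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.0931 with an estimated correlation). The class I antigen-presentation genes H2-D1, from 93.1 ± 3.83 to 304 ± 10.9 CPM, and H2-K1, from 132 ± 7.50 to 249 ± 7.26 CPM, rose, while Ifit3b stayed low at 1.99 ± 0.352 CPM. For immediate early genes, 18 rose, 3 fell and 7 did not pass (18 and 3 adjusted over the list alone, camera adjusted p = 2.51e-06, adjusted p = 0.0934 with an estimated correlation), with Junb up from 16.9 ± 1.67 to 94.5 ± 5.57 CPM and Nr4a1 from 7.34 ± 1.06 to 43.1 ± 4.86 CPM. For YAP/TEAD targets, 17 rose, 5 fell and 3 did not pass (17 and 6 adjusted over the list alone, camera adjusted p = 8.35e-04, adjusted p = 0.0711 with an estimated correlation), with Ccn1 up from 135 ± 9.61 to 253 ± 11.1 CPM and Nt5e down from 73.5 ± 3.80 to 13.0 ± 0.903 CPM. WNT targets did not pass: 11 rose, 2 fell and 6 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.0849), although without day 6 A the camera adjusted p was 0.0477 (0.0477 to 0.121 leaving out each library in turn). For p53 targets, 19 rose, 8 fell and 11 did not pass (19 and 8 adjusted over the list alone, camera adjusted p = 0.392), with Trp53inp1 up from 36.8 ± 6.89 to 149 ± 6.25 CPM and Cdkn1a down from 199.5 ± 16.8 to 64.4 ± 6.12 CPM.

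Between day 6 and control, 7343 genes (54.3%) differed, 3614 higher and 3729 lower, and 1792 by at least 2-fold (978 higher, 814 lower). With limma on log2(TPM + 1) the split tilted, with 61.9% of 5718 genes higher against 49.2% in edgeR.

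At day 12 contractile genes were among those that rose, with some matrix genes. Smooth muscle actin (Acta2) rose from 3.11 ± 0.429 to 293 ± 26.4 CPM, a log2 fold change of 6.54 ± 0.15 (edgeR adjusted p = 6.35e-17), Tagln from 1.68 ± 0.357 to 54.2 ± 11.001 CPM and Myl9 from 39.2 ± 2.26 to 459 ± 16.2 CPM. Ltbp2, a microfibril-associated protein, rose from 0.505 ± 0.0819 to 71.4 ± 6.72 CPM, the proteoglycan gene Dcn from 0.246 ± 0.153 to 17.8 ± 1.33 CPM and Id3 from 17.4 ± 1.68 to 196 ± 7.99 CPM. Cdh16 fell from 1103 ± 53.5 to 37.9 ± 3.67 CPM, Anpep from 114 ± 2.75 to 7.11 ± 0.522 CPM and Lrp2 from 268 ± 17.2 to 95.9 ± 2.88 CPM. Genes of cholesterol synthesis were lower still, with Hmgcs1 going from 435 ± 18.8 to 100.2 ± 2.06 CPM. The edgeR adjusted p of these genes lay between 1.38e-33 and 6.35e-17.

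Cxcl15 was at least 201-fold higher than control at 23.6 ± 1.99 CPM, and Nts was 415-fold higher at 71.2 ± 6.94 CPM (edgeR adjusted p = 5.01e-27). Actg2, a smooth muscle gamma actin gene that can share reads with other actins, went from 1 count in control to 597, a ratio of 559 (95% counting interval 99.9 to 22108). Serpind1 had a ratio of 356 (98.3 to 2946). The p200-family genes Ifi203 (273-fold higher) and Ifi205 (ratio 275, 75.7 to 2274) have similar copies and are uncertain. Angptl1 was at least 140-fold lower, Klhl14 319-fold, Slc6a18 230.4-fold, Kcnj16 147-fold, Kif12 136-fold and the semaphorin gene Sema5b 117-fold lower.

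Among the 28 mesenchymal genes, 21 rose, 2 fell and 5 did not pass (21 and 2 adjusted over the list alone, camera adjusted p = 3.72e-19), with a median log2 fold change of 1.44. For TGF-beta targets, 23 rose, 2 fell and 7 did not pass (23 and 2 adjusted over the list alone, camera adjusted p = 1.50e-16), with Thbs1 up from 313 ± 7.90 to 1024 ± 27.7 CPM. Fibroblast and smooth muscle markers were higher as a group: 9 rose, 3 fell and 2 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 4.35e-05, adjusted p = 0.0811 with an estimated correlation). Postn had a ratio of 97.3 (95% counting interval 26.6 to 809). For proximal tubule differentiation, 15 fell, 5 rose and 6 did not pass (15 and 5 adjusted over the list alone, camera adjusted p = 3.21e-07), with a median log2 fold change of -1.31. For epithelial identity and junctions, 26 fell, 10 rose and 6 did not pass (26 and 10 adjusted over the list alone, camera adjusted p = 8.23e-07), with Ctnnb1 up from 391 ± 12.7 to 1160.5 ± 21.5 CPM. For injured proximal tubule genes, 24 rose, 7 fell and 8 did not pass (24 and 7 adjusted over the list alone, camera adjusted p = 0.00119). Clu, which encodes a secreted chaperone, rose there from 285 ± 18.3 to 871 ± 21.5 CPM and Akap12 fell from 1567 ± 57.4 to 274 ± 13.6 CPM.

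For NF-kB and inflammatory genes, 26 rose, 3 fell and 7 did not pass (26 and 3 adjusted over the list alone, camera adjusted p = 2.33e-09). Tnfaip3 reached 114 ± 2.39 CPM, Saa3 rose from 0.982 ± 0.0494 to 76.2 ± 2.46 CPM, the NF-kB inhibitor gene Nfkbia from 26.4 ± 3.10 to 94.3 ± 1.29 CPM and Cxcl16 from 18.2 ± 0.695 to 72.1 ± 4.10 CPM. For the interferon response, 32 rose, 4 fell and 16 did not pass (33 and 6 adjusted over the list alone, camera adjusted p = 2.34e-04), with H2-D1 up from 93.1 ± 3.83 to 345 ± 2.80 CPM and Ifit3b at 1.54 ± 0.325 CPM. For p53 targets, 19 rose, 5 fell and 14 did not pass (20 and 5 adjusted over the list alone, camera adjusted p = 0.00414, adjusted p = 0.174 with an estimated correlation). Fas, a death receptor gene, rose from 0.507 ± 0.445 to 16.9 ± 1.76 CPM, Ccng1 from 51.1 ± 6.81 to 153 ± 12.9 CPM and Trp53inp1 from 36.8 ± 6.89 to 183 ± 6.85 CPM. For immediate early genes, 16 rose, 3 fell and 9 did not pass (17 and 3 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.240 with an estimated correlation), with Junb up from 16.9 ± 1.67 to 71.0 ± 2.46 CPM. For WNT targets, 11 rose, 2 fell and 6 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.0375, adjusted p = 0.321 with an estimated correlation), with Cd44 up from 62.6 ± 4.27 to 176 ± 12.8 CPM and Lef1 from 0.962 ± 0.485 to 7.90 ± 0.529 CPM, while Wnt7b fell from 46.0 ± 3.75 to 15.4 ± 0.725 CPM. That call was lost without control A (camera adjusted p = 0.0553, 0.0254 to 0.0553 leaving out each library in turn) and with every library thinned to the shallowest (0.108). For YAP/TEAD targets, 14 rose, 8 fell and 3 did not pass (14 and 8 adjusted over the list alone, camera adjusted p = 0.0716), and the camera adjusted p was 0.0357 without control C, 0.0389 without day 12 A and 0.0378 without day 12 C (0.0357 to 0.112 leaving out each library in turn).

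For cholesterol synthesis and uptake, 29 fell, 2 rose and 1 did not pass (29 and 2 adjusted over the list alone, camera adjusted p = 6.78e-28), the smallest camera p of any list and day. Elovl6 fell from 96.1 ± 7.30 to 9.68 ± 1.52 CPM and Sqle from 320.3 ± 8.30 to 82.8 ± 4.58 CPM. For glycolysis, 21 fell, 0 rose and 2 did not pass (21 and 0 adjusted over the list alone, camera adjusted p = 4.22e-06, adjusted p = 0.112 with an estimated correlation), with Gapdh down from 2894 ± 222 to 1805 ± 26.8 CPM. For oxidative phosphorylation, 51 fell, 0 rose and 11 did not pass (53 and 0 adjusted over the list alone, camera adjusted p = 1.28e-06, adjusted p = 0.238 with an estimated correlation), with Atp5b down from 1394 ± 62.5 to 848 ± 31.1 CPM. For G2 and mitosis, 45 fell, 0 rose and 9 did not pass (45 and 0 adjusted over the list alone, camera adjusted p = 2.71e-09), with Plk1 down from 138 ± 6.35 to 61.2 ± 5.55 CPM. For S phase, 30 fell, 2 rose and 18 did not pass (30 and 2 adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.321 with an estimated correlation), with Tyms down from 105 ± 2.15 to 63.0 ± 2.47 CPM. For NRF2 targets, 18 fell, 6 rose and 6 did not pass (19 and 7 adjusted over the list alone, camera adjusted p = 0.0393, adjusted p = 0.0931 with an estimated correlation), and without day 12 B the camera adjusted p was 0.0555 (0.0273 to 0.0555 leaving out each library in turn). Glutathione reductase (Gsr) fell from 270.5 ± 7.37 to 77.4 ± 3.27 CPM, while Cyp1b1, a target of the aryl hydrocarbon receptor, rose from 1.27 ± 0.214 to 78.1 ± 3.36 CPM. For the hypoxia response, 14 fell, 6 rose and 5 did not pass (14 and 6 adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.281 with an estimated correlation). Its member Hif1a, which encodes the oxygen-sensitive factor itself, rose from 174 ± 4.28 to 555 ± 17.4 CPM. The unfolded protein and integrated stress response did not pass: 18 fell, 12 rose and 10 did not pass (18 and 13 adjusted over the list alone, camera adjusted p = 0.513).

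Between day 12 and control, 7133 genes (52.8%) differed, 3532 higher and 3601 lower, and 1853 by at least 2-fold (1045 higher, 808 lower). Over the 3 days, 42 of the 96 list tests passed with the preset correlation, 18 of these 42 also passed with an estimated correlation, and in no passing test did median, mean and test differ in sign, which happened in 14 others.

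**Figure D3:**
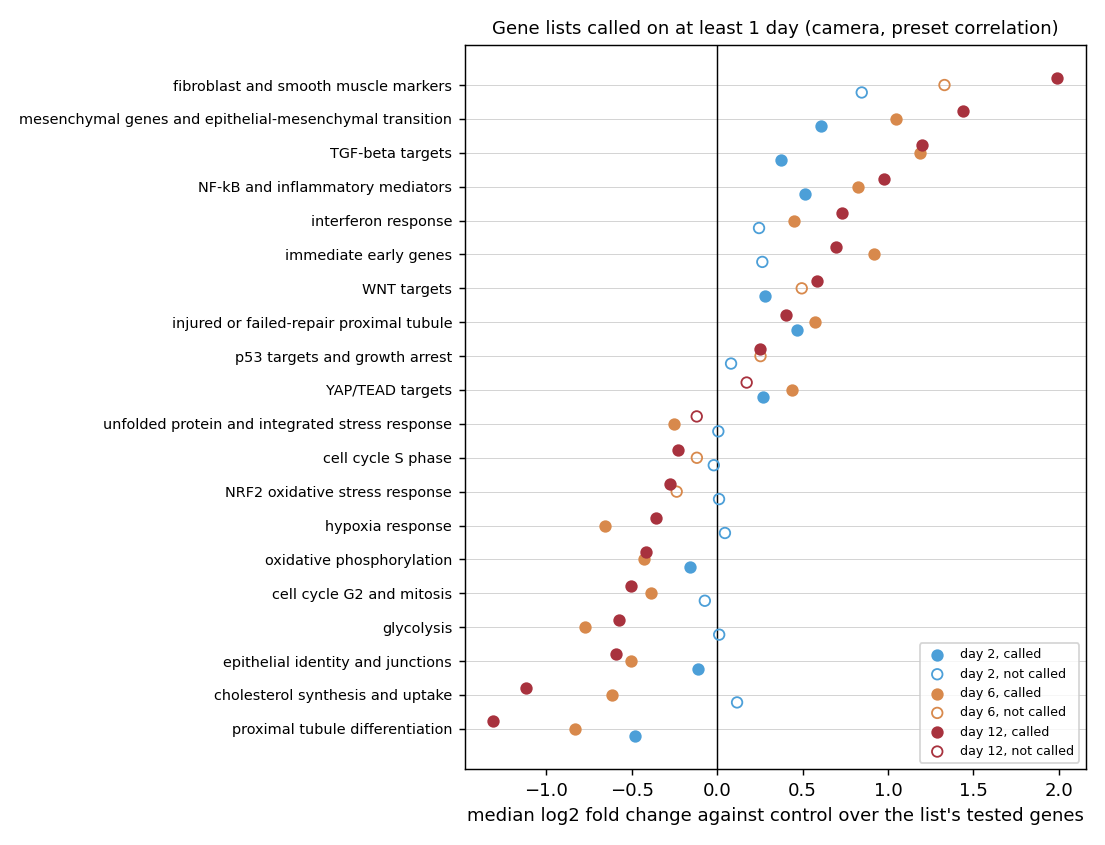
Median log2 fold change against control (horizontal axis) over the tested genes of each list with a camera adjusted p under 0.05 on at least 1 day (vertical axis, 20 lists), at day 2, day 6 and day 12. Filled points passed and open points did not: the median for mesenchymal genes was 0.61 at day 2 and 1.44 at day 12, and that for proximal tubule genes -0.48 and -1.31.

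The other 12 lists passed on no day, though single members moved widely. Of 20 nephric transcription factors and PAX cofactors, 7 fell, 4 rose and 9 did not pass at day 2 (8 and 5 adjusted over the list alone, camera adjusted p = 0.759). By day 6, 10 rose, 8 fell and 2 did not pass (10 and 8 adjusted over the list alone, camera adjusted p = 0.575). By day 12, 8 rose, 8 fell and 4 did not pass (8 and 8 adjusted over the list alone, camera adjusted p = 0.811). Maf rose to 316 ± 17.5 CPM and the Iroquois factor Irx3 fell from 88.8 ± 10.2 to 22.2 ± 1.40 CPM at day 12. Of 20 progenitor and early nephron genes, 9 rose, 6 fell and 5 did not pass at day 2 (9 and 6 adjusted over the list alone, camera adjusted p = 0.118). By day 6, 10 rose, 8 fell and 2 did not pass (10 and 9 adjusted over the list alone, camera adjusted p = 0.333). By day 12, 10 rose, 5 fell and 5 did not pass (10 and 5 adjusted over the list alone, camera adjusted p = 0.270). The growth factor gene Gdnf rose from 1.28 ± 0.153 to 15.2 ± 1.51 CPM at day 12. Of 49 genes of matrix and basement membrane, 19 rose, 17 fell and 13 did not pass at day 2 (22 and 20 adjusted over the list alone, camera adjusted p = 0.959). By day 6, 21 fell, 21 rose and 7 did not pass (21 and 21 adjusted over the list alone, camera adjusted p = 0.753). By day 12, 24 rose, 17 fell and 8 did not pass (24 and 17 adjusted over the list alone, camera adjusted p = 0.270). Col18a1 fell from 1002 ± 49.0 to 281 ± 12.9 CPM at day 12. Of 33 genes of the BCL2 family and cell survival, 4 rose, 4 fell and 25 did not pass at day 2 (6 and 4 adjusted over the list alone, camera adjusted p = 0.811). By day 6, 13 rose, 7 fell and 13 did not pass (13 and 7 adjusted over the list alone, camera adjusted p = 0.783). By day 12, 14 rose, 8 fell and 11 did not pass (14 and 8 adjusted over the list alone, camera adjusted p = 0.502). Bcl2 rose from 20.8 ± 0.810 to 43.7 ± 2.18 CPM at day 12. Of 46 genes of fatty acid oxidation and peroxisomes, 9 fell, 6 rose and 31 did not pass at day 2 (9 and 6 adjusted over the list alone, camera adjusted p = 0.582). By day 6, 16 rose, 12 fell and 18 did not pass (16 and 12 adjusted over the list alone, camera adjusted p = 0.846). By day 12, 13 fell, 13 rose and 20 did not pass (13 and 15 adjusted over the list alone, camera adjusted p = 0.672). Acsl1 fell from 60.3 ± 1.22 to 24.6 ± 1.93 CPM at day 12. Of 15 oestrogen response genes, 3 fell, 3 rose and 9 did not pass at day 2 (5 and 3 adjusted over the list alone, camera adjusted p = 0.140). By day 6, 4 fell, 3 rose and 8 did not pass (4 and 3 adjusted over the list alone, camera adjusted p = 0.423). By day 12, 6 fell, 3 rose and 6 did not pass (6 and 3 adjusted over the list alone, camera adjusted p = 0.777). Stc2 fell from 128 ± 0.927 to 21.9 ± 0.593 CPM and Igfbp4 rose from 14.3 ± 0.973 to 90.2 ± 2.23 CPM at day 12.

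Of 55 cilium and cyst genes, 7 rose, 2 fell and 46 did not pass at day 2 (6 and 1 adjusted over the list alone, camera adjusted p = 0.353). By day 6, 14 fell, 12 rose and 29 did not pass (14 and 12 adjusted over the list alone, camera adjusted p = 0.805). By day 12, 14 fell, 10 rose and 31 did not pass (14 and 10 adjusted over the list alone, camera adjusted p = 0.759). Pkd1 rose from 121.97 ± 9.32 to 225 ± 3.07 CPM and Gli2 from 1.32 ± 0.198 to 20.998 ± 1.26 CPM at day 12. Among 11 loop of Henle and distal tubule markers, 3 fell, 3 rose and 5 did not pass at day 2 (4 and 3 adjusted over the list alone, camera adjusted p = 0.0947). By day 6, 5 fell, 6 rose and 0 did not pass (5 and 6 adjusted over the list alone, camera adjusted p = 0.796). By day 12, 4 fell, 5 rose and 2 did not pass (5 and 5 adjusted over the list alone, camera adjusted p = 0.803). Slc12a2 rose from 132 ± 5.72 to 395 ± 5.12 CPM at day 12. Among 9 collecting duct markers, 3 fell, 1 rose and 5 did not pass at day 2 (3 and 1 adjusted over the list alone, camera adjusted p = 0.631). By day 6, 6 fell, 1 rose and 2 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.181). By day 12, 4 fell, 1 rose and 4 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.270). Aqp6 had no count left at day 12, at least 64.1-fold lower than its control level of 7.08 ± 0.251 CPM. Among 15 podocyte and parietal epithelium markers, 4 rose, 3 fell and 8 did not pass at day 2 (4 and 4 adjusted over the list alone, camera adjusted p = 0.737). By day 6, 10 rose, 3 fell and 2 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.140). By day 12, 9 rose, 2 fell and 4 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.140). Thsd7a rose from 9.04 ± 1.26 to 48.4 ± 1.78 CPM and Cldn1 fell from 41.2 ± 2.24 to 9.44 ± 0.813 CPM at day 12. Only 5 endothelial and 7 leukocyte markers were abundant enough to test. Of the endothelial ones, 1 rose, 1 fell and 3 did not pass at day 2 (1 and 1 adjusted over the list alone, camera adjusted p = 0.811). By day 6, 2 fell, 1 rose and 2 did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.753). By day 12, 2 fell, 1 rose and 2 did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.672). Ramp2 fell from 10.7 ± 0.308 to 1.97 ± 0.425 CPM at day 12. Of the leukocyte ones, 2 fell, 1 rose and 4 did not pass at day 2 (2 and 1 adjusted over the list alone, camera adjusted p = 0.723). By day 6, 3 fell, 1 rose and 3 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.723). By day 12, 1 fell, 3 rose and 3 did not pass (1 and 3 adjusted over the list alone, camera adjusted p = 0.846). Csf1r fell from 18.6 ± 1.13 to 7.68 ± 0.145 CPM at day 12. The day 2 calls of Cd74 (higher), H2-Eb1 and Csf1r (both lower) were lost under several alternatives. Without day 2 C their edgeR adjusted p was 0.0795, 0.0994 and 0.05145. With DESeq2 the adjusted p was 0.0627, 0.101 and 0.167. Leaving out any 1 of the 6 libraries compared ended the Csf1r call (edgeR adjusted p from 0.05145 to 0.223).

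Contrasts between treated days asked how expression moved on. From day 2 to day 6, Serpind1 rose 71.1-fold, Cxcl15 54.1-fold, Pdgfrl 31.7-fold and Slc7a2 29.0-fold. Slc6a18 fell at least 106-fold, Kif12 26.4-fold, the peptide hormone gene Apln 9.11-fold and Aoc1 8.39-fold, and the edgeR adjusted p of these genes lay between 1.02e-22 and 5.74e-10. From day 6 to day 12, the cornified envelope gene Sprr1a rose 8.34-fold, from 2.24 ± 0.214 to 18.9 ± 0.505 CPM (edgeR adjusted p = 8.21e-15), Actg2 7.50-fold, Ifi203 5.56-fold and Ifi205 5.46-fold. The matrix gene Hmcn1 fell 3.32-fold, Peg10 3.15-fold and Homer2 2.84-fold. From day 2 to day 12, Dcn, with no count at day 2, rose at least 138-fold, Serpind1 122.1-fold, Cxcl15 86.6-fold and Ifi205 41.2-fold. Kif12 fell 39.9-fold, Slc6a18 38.9-fold, Cdh16 12.0-fold and the epithelial factor Ehf 11.02-fold. As before, Actg2, Ifi203 and Ifi205 are uncertain.

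From day 2 to day 6, 6062 genes differed (3055 higher, 3007 lower), from day 6 to day 12 2971 (1482 higher, 1489 lower), of which 270 by at least 2-fold, and from day 2 to day 12 5931 (3009 higher, 2922 lower). Across the 4 groups, 8795 genes (65.1%) differed. With limma on log2(TPM + 1) the median of all genes from day 2 to day 6 was shifted by 0.115, and the share of higher calls was 70.9% there, against 50.4% in edgeR. For day 12 against day 2 it was 63.0% against 50.7%, and for day 12 against day 6 it was 36.0% of 1379 genes against 49.9%, with 1793 genes at an edgeR adjusted p under 0.01.

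The days shared much of their response. Of the 2860 genes called at day 2, 2323 were called in the same direction at day 6 (1136 higher, 1187 lower), where lists drawn independently would share 777, and 2268 at day 12 (1092 higher, 1176 lower), against 755. Day 6 and day 12 shared 5643 genes in direction (2768 higher, 2875 lower), against 1938. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.74 for days 2 and 6 (covariance 0.424), 0.72 for days 2 and 12 (0.435) and 0.92 for days 6 and 12 (0.994). In 20 simulations of unchanged groups against the same controls, the mean r was 0.495, 0.493 and 0.520 and the mean covariance 0.0388, 0.0384 and 0.0395. The 3 control libraries cannot be split into parts of at least 2 each, so part of the excess over independent lists can come from the shared controls. Day 2 against control and day 12 against day 6 share no library, and they had 541 genes in the same direction and 509 in opposite directions, against 314 each for independent lists (r = 0.05). At day 12, 1347 of the 2860 genes lay further from control than at day 2 and 498 nearer by the edgeR test between the days. Cdh16 was among the former, at 454.2 ± 19.8 CPM and then 37.9 ± 3.67 CPM, with a 12.0-fold fall (edgeR adjusted p = 1.69e-29).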

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

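The tests of the patterns in this part were chosen only after the results were seen, except the comparisons with other splits of the libraries. Genes named here, other than Pax8, Pax2 and Hnf4a and members of the lists, were chosen after their values were seen.

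Some genes moved to opposite sides of control at different days, with the difference between the days past an edgeR adjusted p of 0.05. Against control, 60 genes were higher at day 2 and lower at day 6, 67 lower at day 2 and higher at day 6, 70 higher at day 2 and lower at day 12, and 72 lower at day 2 and higher at day 12. Such genes were fewer than independent lists would give, 127 against 777 for days 2 and 6 and 142 against 755 for days 2 and 12. Id3, an inhibitor of basic helix-loop-helix factors, went from 17.4 CPM in control to 11.1, 84.5 and 195.7 CPM at days 2, 6 and 12. Sulf2 went from 85.6 to 32.5, 68.8 and 152 CPM and Clu from 285 to 191, 604.1 and 871 CPM. In the other direction, the sterol genes Cyp51 (154.8 CPM in control, 198 at day 2, 50.6 at day 12) and Insig1 (143.9, 189 and 52.5 CPM) and the regulator Srebf2 (639.7, 734 and 286 CPM) rose before they fell. The hepatocyte growth factor receptor gene Met (230.2, 334 and 125.6 CPM) and the matrix gene Vcan (65.3, 121 and 27.7 CPM) did so as well.

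The Pax8 transcript was not lower in treated libraries and was 0.83 higher on the log2 scale at day 2. Reads shared with Pax2 would keep Pax8 high where Pax2 is high, but Pax8 changed by -0.6467 on the log2 scale from day 2 to day 6 while Pax2 was not lower. The low depth of day 2 B does not account for the rise, which was 0.7291 without that library. Reads from Pax8 exons outside the deleted part cannot be told apart from intact transcript, because the tables hold 1 value per gene and the day 2 change of 0.8296 sums over exons. Whether loss of the protein could raise transcription of its own gene was not tested.

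Hnf4a stood at 12.8 CPM in control, 1.03 at day 2, 0.303 at day 6 and 2.05 at day 12, and day 12 was higher than day 6 (edgeR adjusted p = 9.80e-05, 6.48-fold higher). Outgrowth of cells that kept PAX8 would return every lost gene by about the same share only if each fall came from PAX8 loss. The design cannot separate that loss from drug, Cre activity and time in culture. Hnf4a regained 14.0% ± 5.90 of its loss, while the median over the 62 genes at least 8-fold lower at day 6 with at least 10 CPM in control was -0.007% (quartiles -1.87% and 2.01%), Slc6a18 regained 0.421% and Cdh16 -4.17%, and 2 of the 62 genes, Hnf4a included, regained that much. These shares argue against a joint return of the lost genes, but they do not decide on outgrowth. Hnf4a had 1 to 4 counts per library at day 6 and 12 to 22 at day 12. Counting noise in a low gene is argued against by the highest edgeR adjusted p in the fit and without each of its 6 libraries, 0.002084. A return of Hnf4a with few other genes may be a candidate explanation, and it was not tested further.

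Some smooth muscle and fibroblast genes rose by day 12, Acta2 from 3.11 to 293 CPM and Tagln from 1.68 to 54.2 CPM. As a group these markers passed with the preset correlation but not with an estimated one (camera adjusted p = 0.0811). Outgrowth of contaminating fibroblasts or smooth muscle cells would bring their abundant transcripts, but 4 of the 5 abundant fibroblast genes had no called rise: Col1a1 went from 2.20 to 3.03 CPM (edgeR adjusted p = 0.212), Col1a2 had 0 and 2 counts, and Col3a1 and Lum had 0 in both groups, while Dcn rose to 17.8 CPM; of the 14 tested markers 6 are also in another list and 10 reached 1 CPM in control. A lower share of epithelial cells would raise markers of other cell types alike only if those types were present in the line. The median log2 fold change of 12 endothelial and leukocyte markers was -0.3467 against 1.99 for 14 fibroblast and smooth muscle markers (one-sided permutation p = 8.70e-04). The comparison cannot decide the question, because whether endothelial cells or leukocytes were present is not known. The fibroblast and smooth muscle list was also picked because it had risen, and the permutation treats genes as independent. A change in the epithelial cells themselves may be a candidate explanation. Time in culture or the drug cannot be told apart from PAX8 loss, as there were 0 libraries of untreated cells of the same day.

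The counts of changed genes were set beside other splits of the same libraries, refitted on the 6 libraries compared. In each contrast the 10 splits are too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes as the real split. The real and highest other values were 2403 and 1 for day 2 against control, 7423 and 1 for day 6, 7283 and 1 for day 12, 5693 and 0 for day 6 against day 2, 3633 and 0 for day 12 against day 6, and 5590 and 0 for day 12 against day 2. For the test across the 4 groups, 1 of 100 splits of the 12 libraries, the real one, gave 8795 genes or more. That is the smallest share that 100 splits can give. It speaks of the libraries only, since those of a group may come from 1 culture. The highest other split gave 6828 genes.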

How the results depend on the processing

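Thinning to the shallowest library and leaving out mitochondrial genes were tested only after the results were seen, and the other alternatives were planned. No gene allowed by the naming rule and no list test turned direction while past the threshold. Which direction held more genes did turn in 5 of the 6 contrasts. At day 2 against control, with 1392 higher and 1468 lower, it became 1430 and 1403 with relative log expression, 1204 and 1136 with DESeq2, 1461 and 1397 without mitochondrial genes, and 1170 and 1169 without day 2 A. At day 6 against control, relative log expression, DESeq2, both other filters and limma on log2(TPM + 1) gave more higher than lower genes. At day 12 against control this held for relative log expression, no filter, DESeq2, limma on log2(TPM + 1), thinning and without day 12 C (3260 higher, 3248 lower). Without mitochondrial genes, day 6 and day 12 against day 2 gave more lower genes, as did, for day 12 against day 2, the fit on only its 6 libraries and that without day 2 B (2847 higher, 2861 lower). Counts of changed genes stayed within 1.5 times their value in all but 7 cases. With limma on log2(TPM + 1), 1744 genes changed at day 2 (354 at least 2-fold) and 1379 between day 6 and day 12, where an adjusted p under 0.01 gave 1793. Requiring at least 2-fold changes, 496 calls were shared by days 2 and 6, 488 by days 2 and 12 and 1404 by days 6 and 12, fewer by construction. The cause of the TPM values was not tested.

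For day 2, day 6 and day 12 against control, leaving out single libraries gave 2339 to 3083, 6684 to 6924 and 6492 to 6711 genes. For day 6 against day 2 it gave 5331 to 5861, for day 12 against day 6 2062 to 2536 and for day 12 against day 2 5206 to 5708. Without day 2 B, 2632 genes changed at day 2. DESeq2 gave 2340, 6493 and 6255 genes for the 3 days, of which 2302, 6303 and 6051 were shared with edgeR, and fits on only the 6 libraries compared 2403, 7423 and 7283. Thinned to the depth of day 2 B, 2396, 6203 and 5923 genes passed, so depth limits the number of genes called. Without mitochondrial genes there were 2858, 7325 and 7141. The replicate block gave 2932, 7370 and 7164, and the lists of fibroblast and smooth muscle markers at day 6 (camera adjusted p = 0.0419) and YAP/TEAD targets at day 12 (0.0402) passed with it. Letters do not pair the libraries: the median same-letter correlation after removing group means was 1.40e-04, and 3 of 12 libraries were closest to their own letter.

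Among pairs of gene and contrast that the naming rule allowed, not all of which the text names, calls were lost for 24 with limma on log2(TPM + 1), 8 at an adjusted p under 0.01, 6 with DESeq2, 6 when thinned, 2 without a filter, 2 with the replicate block, and 1 each on only the 6 libraries, with relative log expression and without mitochondrial genes. Leaving out single libraries ended 0 to 8 such calls and added 1. Of the 42 list tests that passed, 24 did not with an estimated correlation. With fry, which tests lists without setting them against other genes, 34 more passed. On log2(TPM + 1), 5 more did: the interferon response (0.0153), cholesterol synthesis and uptake (0.0116) and immediate early genes (0.00753) at day 2, and WNT targets (0.0484) and collecting duct markers (0.0460) at day 6 (camera adjusted p).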

Other observations

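Genes grouped by the root of their symbol were tested for day 12 against control, a test chosen before its result was seen, and the members named here were chosen after their values were seen. Of 137 families with at least 10 tested members, 3 passed by camera with the preset correlation. Annexins, which bind membranes in a calcium-dependent way, rose: 7 of 10 were higher and 2 lower (camera adjusted p = 4.11e-04, adjusted p = 0.757 with an estimated correlation). Anxa8 went from 7.53 to 86.6 CPM, Anxa11 from 41.4 to 112 CPM, Anxa5 from 246 to 535 CPM and Anxa6 from 324.5 to 632.5 CPM, while Anxa4 fell from 234.6 to 174 CPM and Anxa1 from 179 to 155 CPM.

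Aldehyde dehydrogenases fell: 10 of 15 were lower and 1 higher (camera adjusted p = 0.00146, adjusted p = 0.757 with an estimated correlation). Aldh1a2, which makes retinoic acid, went from 338 to 83.8 CPM, the folate enzyme gene Aldh1l2 from 102 to 27.4 CPM and Aldh4a1 of proline breakdown from 101.5 to 37.7 CPM, while Aldh1a3 rose from 0.879 to 2.54 CPM. Kruppel-like factors rose, 7 of 12 higher and 0 lower (camera adjusted p = 0.0490, adjusted p = 0.757 with an estimated correlation): Klf7 from 34.1 to 106 CPM, Klf6 from 99.4 to 205 CPM, Klf5 from 15.1 to 37.8 CPM and Klf4 from 15.3 to 28.2 CPM. The counts of higher and lower members were the same with relative log expression size factors and with no scaling. The hypothesis that a family moves as a group beyond chance was met by 3 families with the preset correlation and by 0 with an estimated correlation.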
